A study of Homo sapiens with 6 samples.

How the data were processed

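RNA abundance was measured in MM.1S cells, an established human multiple myeloma line. Cells were exposed to enzastaurin, an inhibitor of protein kinase C beta, for 3, 6 or 12 h, and untreated cells were taken at the same times. Total RNA was converted to biotin-labelled cRNA, per the labels' protocols, and hybridised to Affymetrix arrays, 1 array for each treatment and time, 6 in all. The deposited values are linear probe set intensity values that the authors made with MAS5, per the submitters' processing notes. The MAS5 version and its scaling target are not given in the sources used here, and neither are detection calls, so no call of present or absent was used. All 6 columns of the table were matched to samples through their labels.

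The table held 22277 probe sets, of which 62 were AFFX controls. Of the other 22215, 19064 were paired with 1 gene in the platform annotation, 1043 with several genes and 2108 were not listed. Entrez identifiers of 19052 of the 19064 were found in the RefSeq gene table of assembly GCF_000001405.40 (GRCh38.p14), which was used for names only, and no coordinates are given. No probe set listed with several genes was given a name.

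The authors' scaling was kept, since the medians of log2 intensity differed by 0.12 at most between arrays. Each intensity was floored at 1 and log2 transformed. The floor was set after 22 to 39 exact zeros had been seen on every array, and it touched none of the tested genes. Probe sets in the upper 50 percent of mean log2 intensity were kept, which corresponds to a geometric mean of 63.3 or more. One probe set was kept for each gene, the one with the highest mean, which left 6838 genes. Among 145 named genes, 42 had over 1 kept probe set, and in 6 of them (BCL2, BIRC5, FEN1, RRP12, TLE3 and VDR) these differed in the sign of the mean log2 ratio.

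The effect of enzastaurin was fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend in the prior variance), with the time point as a block. The coefficient is the mean of the 3 time-matched log2 ratios. Its standard error is moderated. It joins how far that ratio differed between times, with 2 residual degrees of freedom, to a prior variance from all genes, with 9.26. A real difference between times therefore counts as error in this fit. Nothing in the labels says that the arrays came from separate cultures or days. The p-values measure the spread between these 6 arrays, which may be partly technical. A slope of the effect on log2 hours was fitted with 1 residual degree of freedom, and the difference between 12 h and 3 h was taken from the additive fit. P-values were adjusted by the Benjamini-Hochberg method, and an adjusted p under 0.05 was called. At single times no test was possible with 1 array on each side, and genes at least 2-fold apart were counted. No standard deviation is given at single times for the same reason.

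Before the data were examined, 23 gene lists were fixed, together with the tests, the alternative settings and the rule for naming genes. The lists held 509 genes, of which 445 had a probe set with 1 symbol and 330 passed the filter. Lists with at least 5 measured members were tested with camera at its preset correlation of 0.01, with camera at an estimated correlation, and with fry. At each time the median log2 ratio of a list was ranked among 10000 random lists of the same size, drawn from 20 bins of mean expression. The result of 1 tested list, which was not called, is not reported here. A percentile of this kind describes a pair of arrays and is not a test of the treatment.

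Named genes were the 15 largest mean ratios in each direction with 1 sign at all 3 times, those past the test first and the rest filled in by size. The 5 highest and 5 lowest ratios at each time were named too, with the 5 largest slopes in each direction past the test and the 3 largest moderated statistics in each direction for 12 h against 3 h. Up to 4 members of each list with the largest mean ratio were named, and CTNNB1, JUN, TP73, DDIT3, HSPA5, ATF4, XBP1, PRKCB, GSK3B, CCND1 and MYC were always included. Genes named from the fit of the 6 h and 12 h pairs, members of a list past the test in it or over the list alone, DEPTOR and the lysosomal and endoplasmic reticulum genes of the closing section were chosen after their values were seen.

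The fits were tested on simulated data for these 6838 genes with known changes. The treatment fit recovered 48 percent of changes of 1 log2 unit and 100 percent of changes of 2 units, and 4.40 percent of its calls were false. The slope fit recovered 32 percent of slopes of 1 and 100 percent of slopes of 2, with 8.79 percent false calls. The fit of 12 h against 3 h recovered 22 percent of changes of 1 and 88 percent of changes of 2, with 3.12 percent false calls. Camera called 1 of 1 simulated shifted list and 0 of 22 unshifted lists. Simulated genes and arrays were independent, so these results leave out correlation between genes and differences shared by whole arrays. Simulated treatment changes were also the same at all 3 times, so the shares recovered do not hold for effects that differ between times. CHAC1, for example, had a mean log2 ratio of 2.65 in the real data and was not called. In the real lists the estimated correlation reached 0.49 (G2/M genes).

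Alternatives planned beforehand were quantile normalization, equal medians of all probe sets, log2 of intensity plus 16, no filter, a stricter filter that kept the highest 33 percent, every probe set tested, probe sets with the suffix _x_at or _s_at left out, eBayes without the intensity trend, robust eBayes, a fit without the time block, and each time-matched pair left out in turn. For lists, the median over all kept probe sets of a gene was a further alternative, and for 2-fold counts a 3-fold limit. Alternatives added after seeing the data were the ribosomal RNA control intensity as a covariate, equal medians of the kept genes, and 12 h against 3 h without the 6 h pair. The number of arrays limits the precision throughout.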

Results

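Gene expression was measured in MM.1S cells, a human multiple myeloma line, after 3, 6 and 12 h with enzastaurin and in untreated cells at the same times. Enzastaurin inhibits protein kinase C beta, and the title of the series links this kinase to beta-catenin, endoplasmic reticulum (ER) stress and apoptosis. There was 1 array for each treatment and time, 3 enzastaurin and 3 untreated arrays in all. Every value below is an Affymetrix MAS5 intensity or a log2 ratio of enzastaurin over untreated cells. Errors are moderated standard errors from limma, for 3 time-matched ratios (n = 3), or 2 in the fit of the 6 h and 12 h pairs (n = 2). They combine a gene's own spread with a prior variance shared by genes of like intensity. For slopes the prior was estimated as infinite, so their errors come from the prior alone. Single times have no replicate.

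The 6 arrays had median intensities from 62.2 to 67.6. The log2 ratio of 3' to 5' probe sets was lowest on the 6 h enzastaurin array, at 0.57 for ACTB and -0.11 for GAPDH, and untreated arrays had 1.16 to 1.89 and 0.23 to 0.30. Probe sets for ribosomal RNA parted the arrays across treatment. Their mean log2 intensity was 11.98 and 9.29 in untreated cells at 6 h and 12 h and 9.99 in enzastaurin cells at 3 h. It was 3.39 in untreated cells at 3 h, and 3.79 and 3.02 in enzastaurin cells at 6 h and 12 h. At 3 h the enzastaurin array thus had the higher ribosomal RNA intensity, and at 6 h and 12 h the untreated array had it.

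The first comparison asked which transcripts enzastaurin altered across all 3 times. RND3, which opposes actin stress fibres, rose 8.54-fold, from intensities of 92.9 to 153 in untreated cells to 673 to 1355 with enzastaurin (mean log2 ratio 3.09, SE 0.35, adjusted p = 0.0165). BHLHE40, a transcriptional repressor that responds to stress and the circadian clock, rose 4.33-fold (2.11, SE 0.30, adjusted p = 0.0388). A weaker BHLHE40 probe set below the filter had smaller log2 ratios of 0.12, 0.86 and 0.66 at 3, 6 and 12 h. LMNB1, which encodes lamin B1 of the nuclear envelope, fell 5.56-fold (-2.48, SE 0.36, adjusted p = 0.0388). TNFAIP8, an inhibitor of apoptosis induced by tumour necrosis factor, fell 3.75-fold (-1.91, SE 0.27, adjusted p = 0.0388). Each of the 4 went 1 way at all 3 times.

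These 4 genes, 2 higher and 2 lower, were the calls among 6838 genes in limma. At an unadjusted p under 0.05 there were 370 genes, 132 higher and 238 lower, where chance gives 342. Without the 6 h or the 12 h pair no gene passed, without the 3 h pair 247 passed, and with the ribosomal RNA intensity as a covariate, added after seeing the data, 74 passed. The fit without the 3 h pair had a prior of 16.86 degrees of freedom, against 9.26 in the reported fit. The covariate fit had a prior estimated as infinite. In limma 398 of its genes had an unadjusted p under 0.05, so the 74 do not show more genes changed. With a variance prior without the intensity trend no gene passed, and with equal medians of all probe sets, no filter or every probe set tested RND3 alone did. BHLHE40 and LMNB1 also did not pass without the time point in the fit.

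Further large ratios of 1 sign at all 3 times did not pass the test. Among the higher ones were several genes of the ATF4 and CHOP stress response. CHAC1, which degrades glutathione, had log2 ratios of 4.78, 0.54 and 2.62 at 3, 6 and 12 h. DDIT3, which encodes CHOP, had 2.25, 1.11 and 1.95, and ATF3 had 2.33, 0.67 and 1.87. DDIT4, an inhibitor of mTORC1, had 1.89, 1.92 and 1.40. The chemokine CCL4 had 3.39, 1.96 and 1.07, and the cell cycle inhibitor CDKN1A had 1.77, 2.10 and 0.84. The mean log2 ratio was 2.26 for IGFBP3, an IGF-binding protein, 1.96 for the kinase SGK1 and 1.67 for PHLDA1. It was 1.57 for the antiviral enzyme OAS3, 1.49 for the receptor subunit IL10RA, 2.03 for DNAAF1 and 1.56 for WHRN. The adjusted p of these 13 genes ran from 0.120 for DDIT4 to 0.401 for DNAAF1.

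On the lower side, DUSP6, a phosphatase of ERK induced by ERK signalling, had log2 ratios of -1.42, -1.62 and -2.12, and all 3 of its probe sets had mean ratios of -1.62 or lower. KIFC1, a mitotic kinesin, had -1.23, -1.95 and -2.58, and HEY1, a Notch target, had -1.16, -2.20 and -2.03. PDIA3, a protein disulfide isomerase of the ER, was at -0.11 at 3 h and at -2.56 at both 6 h and 12 h. The deacetylase HDAC9 had -0.10, -2.67 and -2.56. ZNF652 had a mean log2 ratio of -1.84, AMPD1 -1.70, the vitamin D receptor VDR -1.69 and ID2, an inhibitor of differentiation, -1.66. HIRA had -1.64, TAF15 -1.58, GNAI1 -1.56 and ZNF212 -1.52. AMPD1 at 28.4, GNAI1 at 31.6 and HIRA at 32.1 with enzastaurin at 12 h also lay near the level of T and NK cell markers, so their sizes are not exact. The same holds for HEY1, whose mean intensity over the 6 arrays was only 66.8. The adjusted p of these 13 ran from 0.120 for DUSP6 to 0.427 for VDR, and of the other kept probe sets of VDR 1 had a mean ratio of -1.44 and 2 weaker ones had 0.22 and 0.04.

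**Figure D1:**
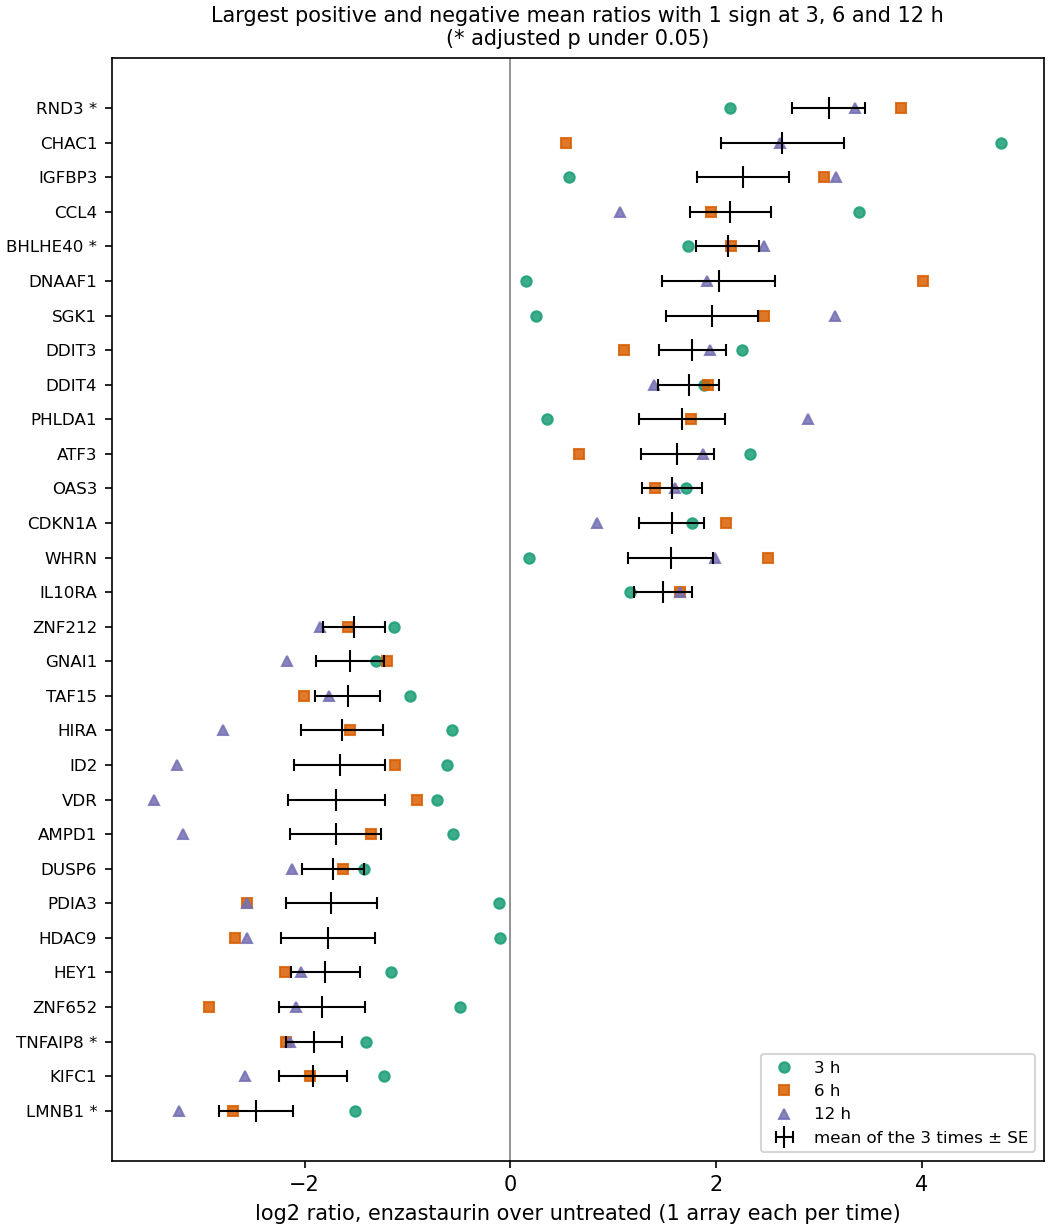
Log2 ratios of enzastaurin over untreated cells (x axis) for the 15 largest mean ratios in each direction that had 1 sign at all 3 times (y axis, genes). Coloured symbols are the ratios at 3, 6 and 12 h, each from 1 array per treatment, black bars are the mean ± SE, and an asterisk marks the 4 genes past an adjusted p of 0.05, with RND3 at 3.09 and LMNB1 at -2.48 as the ends.

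Genes that the naming rule always included were looked at one by one. CTNNB1, which encodes beta-catenin, had intensities of 770, 845 and 517 in untreated cells and 428, 1141 and 719 with enzastaurin (mean log2 ratio 0.02, SE 0.32). Its log2 ratios were -0.85, 0.43 and 0.47 at 3, 6 and 12 h. PRKCB, the drug's target, lay near the filter at 44.5 to 89.8 and had ratios of 0.38, -0.38 and -0.68. GSK3B had a mean log2 ratio of -0.20. JUN was at 321 to 427 in untreated cells and at 718 to 859 with enzastaurin (1.06, SE 0.29, adjusted p = 0.402), and MYC had ratios of -0.66, -0.53 and -2.09 (-1.09, SE 0.30, adjusted p = 0.427). TP73 at intensities of at most 30.9 and CCND1 at 29.0 to 54.8 lay below the filter and were not tested. Among ER stress genes, HSPA5, the main ER chaperone, had ratios of 0.08, 0.32 and -0.61, XBP1 -0.10, 0.46 and 0.26, and ATF4 0.52, 0.07 and 0.17.

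At 6 h and 12 h the responses resembled each other more than either resembled 3 h. Across the 6838 genes, which are not independent replicates, log2 ratios at 6 h and 12 h correlated at 0.44 (Pearson). Those at 3 h correlated with 6 h at -0.21 and with 12 h at -0.14. The fit of the 6 h and 12 h pairs alone called 247 genes, 105 higher and 142 lower, and 159 of them had the opposite sign at 3 h. Its prior had 16.86 degrees of freedom, so its errors and p-values rest mostly on the spread of other genes. In these 2 pairs the ribosomal RNA intensity went with the treatment, and so did the ACTB 3' to 5' log2 ratio, at 0.57 and 0.86 with enzastaurin against 1.16 and 1.60 in untreated cells.

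Higher in this fit of 2 pairs were MTSS1, an actin-binding protein (log2 ratio 4.52, SE 0.40, adjusted p = 7.55e-06), RND3 (3.58), the lymphocyte receptor CD6 (3.30), STAT4 (3.16), IGFBP3 (3.11), DNAAF1 (2.96), SGK1 (2.82) and GADD45A (2.17). At 3 h the ratio was -0.64 for MTSS1, -1.71 for CD6 and -0.79 for STAT4, and 0.57 for IGFBP3 and 0.25 for SGK1. MTSS1, CD6 and STAT4 were also high in untreated cells at 3 h, at 147, 166 and 456, against 9.29, 49.7 and 90.0 in untreated cells at 6 h. The untreated MTSS1 intensities of 9.29 and 17.5 at 6 h and 12 h are no higher than the 18.6 to 28.0 of monocyte markers, so the size of its ratio and its rank are not exact. A weaker probe set of MTSS1 had ratios of -0.33, 0.30 and 1.30, and a second of CD6 had -0.09, 0.34 and 1.34.

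Lower in the same fit were the potassium channel KCNN3 (-3.87, SE 0.40, adjusted p = 1.85e-05), the pentose phosphate enzyme TKT (-3.33, SE 0.33, adjusted p = 1.43e-05), LMNB1 (-2.96), HDAC9 (-2.62), the phosphatase PTPN6 (-2.60), PDIA3 (-2.56), the mTOR inhibitor DEPTOR (-2.51) and the Ras activator RASGRP3 (-2.50). KCNN3 was at 24.1 and 15.5 with enzastaurin at 6 h and 12 h, the level of those markers, so the size of its ratio is not exact either, and its second kept probe set had ratios of 0.60, -1.13 and -2.89. TKT was at 623 to 1009 in all untreated cells and at 782 after 3 h of enzastaurin, and fell to 93.5 at 6 h and 93.3 at 12 h, and its second probe set had ratios of -3.16 and -2.97 at these times. The plasma cell genes IRF4 (-1.60), TNFRSF17, which encodes BCMA (-2.05), ITGA4 (-1.85) and SDC1 (-1.04) were called lower in this fit as well, and CCND2 (0.77) higher.

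**Figure D2:**
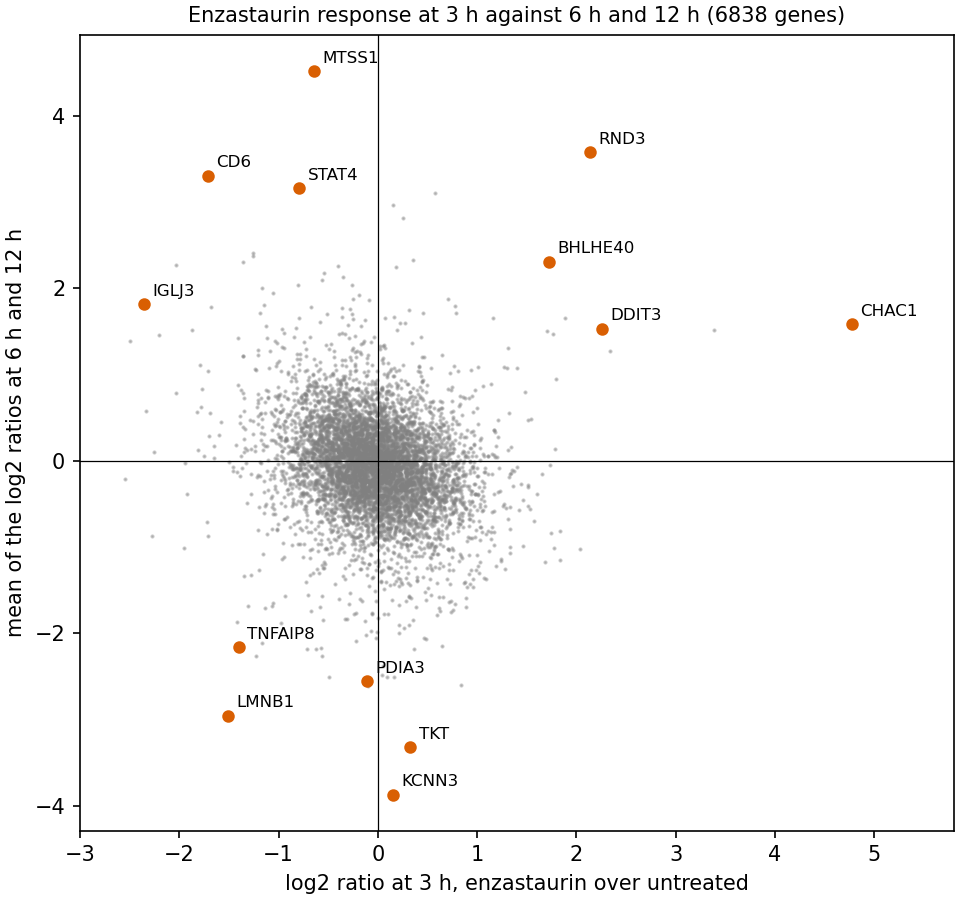
Log2 ratio of enzastaurin over untreated cells at 3 h (x axis) against the mean of the log2 ratios at 6 h and 12 h (y axis), 1 grey point for each of 6838 genes and 13 genes named in orange. RND3, BHLHE40, DDIT3 and CHAC1 lie above 0 on both axes and LMNB1 and TNFAIP8 below, while MTSS1, CD6 and STAT4 are below 0 at 3 h and TKT, KCNN3 and PDIA3 lie near 0 at 3 h.

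Whether the effect was higher or lower at later times was asked through its slope per doubling of hours. Such a slope does not tell a steady change from a step after 3 h. TKT, called below, had ratios of 0.33, -3.43 and -3.22 at 3, 6 and 12 h. The slope passed the test in 98 genes, 35 upward and 63 downward. Upward slopes were largest in CD6 (2.73, SE 0.39, adjusted p = 2.74e-08), MTSS1 (2.64), SERPINA1 (2.43), DEPP1 (2.05) and the immunoglobulin light chain probe set IGLJ3 (2.04). CD6 at 28.0, SERPINA1 at 20.7 and MTSS1 at 17.5 in untreated cells at 12 h lay at or below the level of monocyte markers, so the size and rank of these slopes are not exact, and the same holds for KCNN3 and HLA-DOB (28.3 with enzastaurin at 12 h) below. Downward slopes were largest in KCNN3 (-2.22, SE 0.40, adjusted p = 3.76e-05), PTPN6 (-2.05), the class II genes HLA-DOB (-1.93) and HLA-DPB1 (-1.90), and TKT (-1.77). HLA-DPB1 went from a ratio of 1.28 at 3 h to -2.52 at 12 h.
Among members of the fixed lists, the slope called TNFRSF17 and ITGB7 downward and JCHAIN upward in plasma cell genes, and EDEM1 upward and SDF2L1 downward in ER chaperones. SLC7A11, MARCKS, GADD45A, PHLDA1 and CENPE were called upward and PERP, SRM and TKT downward. CASP8 of the apoptosis regulators was called upward, and both of its kept probe sets had ratios of 2.34 or more at 12 h. The ribosomal RNA intensity was higher with enzastaurin at 3 h and lower at 6 h and 12 h. With equal medians of the kept genes, an alternative added after seeing the data, 0 slopes passed in limma and 675 had an unadjusted p under 0.05, and with quantile normalization 7 passed.

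Between 12 h and 3 h, over both treatments, 0 of 6838 genes passed in limma and 148 had an unadjusted p under 0.05, where chance gives 342. This additive fit counts a treatment effect that differs between times as error, so the 0 does not show that no gene changed. The largest moderated statistics belonged to the membrane protein EMP3 (log2 difference 1.59), the transporter SLC38A7 (1.55) and the cytokine receptor chain IL2RG (1.19) on the higher side. On the lower side they belonged to LMNB1 (-1.83), the apoptosis activator BCL2L11 (-1.84) and DDIT4 (-1.81). None had an adjusted p under 0.999.

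At each time the arrays were also set side by side. After 3 h, 129 genes were at least 2-fold higher and 181 at least 2-fold lower with enzastaurin, a balance that turned with quantile normalization (from 58.4 to 47.3 percent lower) and with equal medians of all probe sets (48.0). The highest ratios were those of CHAC1 (4.78), CCL4 (3.39), ATF3 (2.33), DDIT3 (2.25) and RND3 (2.13). CHAC1 had an untreated intensity of 25.4 at 3 h, the level of monocyte markers, so its ratio and rank are not exact. The lowest included the mitotic kinesins KIF20A (-2.54) and CENPE (-2.34), with RTP4 (-2.50), IGLJ3 (-2.35) and the interferon-induced GTPase GBP1 (-2.28).

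After 6 h, 383 genes were at least 2-fold higher and 220 lower, and with equal medians of all probe sets the share of lower genes moved from 36.5 to 50.5 percent. MTSS1 (4.40), DNAAF1 (4.01), RND3 (3.80), RPGR (3.26) and PLCD1 (3.19) had the highest ratios. KCNN3 (-3.47), TKT (-3.43), ZNF652 (-2.93), LMNB1 (-2.70) and HDAC9 (-2.67) had the lowest. After 12 h, 265 genes were at least 2-fold higher and 712 lower. MTSS1 (4.64), CD6 (3.75), SERPINA1 (3.61), RND3 (3.35) and STAT4 (3.20) stood highest, and KCNN3 (-4.28), VDR (-3.46), PTPN6 (-3.26), ID2 (-3.24) and LMNB1 (-3.22) lowest. The ratios and ranks of MTSS1 and KCNN3 at both times, of RPGR and PLCD1 at 6 h (untreated 20.4 and 21.2) and of CD6 and SERPINA1 at 12 h (untreated 28.0 and 20.7) are not exact, since 1 side lies at or below the level of monocyte markers. At 12 h the median ratio over all kept genes was -0.18, against -0.04 at 3 h and 0.06 at 6 h. With equal medians of the kept genes, the share of lower genes at 12 h moved from 72.9 to 49.7 percent. At 6 h and 12 h together, 95 genes were at least 2-fold higher at both times and 127 lower at both, where independent ratios would give 14.8 and 22.9.

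Of 21 tested gene lists fixed beforehand, 7 were called by camera at its preset correlation. None of the 7 calls held with an estimated correlation (smallest adjusted p = 0.592 with an estimated correlation), and fry called none (smallest adjusted p = 0.330). With an estimated correlation camera rests on the 2 residual degrees of freedom, so a call among 21 lists was hard to reach. The immediate early list had an estimated correlation of -0.06, below the preset, and its unadjusted camera p still rose from 0.00015 to 0.056. The heat shock list had -0.04. In the other called lists the estimate lay above the preset of 0.01. It was 0.49 for G2/M, 0.32 for cholesterol, 0.28 for ribosome biogenesis, 0.11 for ATF4 and CHOP and 0.06 for FOXO genes. For these lists the p-values of camera at the preset may be too small. The ATF4 and CHOP stress response, induced by eIF2alpha phosphorylation, was higher as a group (adjusted p = 2.56e-12, and adjusted p = 0.592 with an estimated correlation). Its median log2 ratio was 0.48, with medians of 0.38, 0.47 and 0.66 at 3, 6 and 12 h, and each lay above at least 99.97 percent of random lists. Of 26 measured members 22 had a mean ratio above 0 and 15 were higher at all 3 times. None passed over all genes, and 5 passed when adjusted over the list alone, namely DDIT3, DDIT4, ATF3, CHAC1 and the amino acid transporter subunit SLC3A2 (1.30). The transporter SLC7A5 went the other way, with ratios of 0.36, -1.72 and -1.97.

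ER chaperones and ER-associated degradation, the branch driven by ATF6 and XBP1, were not called (adjusted p = 0.244, median 0.03, 12 of 23 members above 0, mean -0.00, test direction up). Their medians were 0.13, 0.19 and -0.21, above 97.3, 93.2 and 49.8 percent of random lists. Beside PDIA3, the largest mean ratios were those of DNAJC3 (0.92), SDF2L1 (-0.68) and EDEM1 (0.57). No member passed over all genes, and none when adjusted over the list alone. At the preset correlation the list was called without the 12 h pair (adjusted p = 0.0178), with every probe set tested (0.00690) and with the median over probe sets (0.0314). In the reported fit its adjusted p was 0.734 in camera with an estimated correlation and 0.807 in fry.

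Immediate early and AP-1 genes were higher as a group (adjusted p = 0.00105, median 0.53, and adjusted p = 0.592 with an estimated correlation), with 10 of 14 members above 0. No member passed over all genes. Adjusted over the list alone, JUN (1.06), JUND (0.97), DUSP1 (0.93) and PHLDA1 passed upward and DUSP6 downward. The call was lost without _x_at and _s_at probe sets (adjusted p = 0.0641), where the median was 0.12. Cholesterol synthesis and LDL uptake genes were higher as a group (adjusted p = 0.0190, median 0.09, and adjusted p = 0.713 with an estimated correlation), with medians of 0.33, 0.32 and -0.24. These medians lay above 99.9, 96.5 and 51.0 percent of random lists at 3, 6 and 12 h. SC5D (0.71), DHCR7 (0.69), SQLE (0.49) and INSIG1 (0.44) had the largest mean ratios, and none of the 15 members passed either way of adjusting. This call was lost without the 3 h pair (adjusted p = 0.407), without the 6 h pair (0.0599) and without _x_at and _s_at probe sets (0.0792).

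FOXO, heat shock, G2/M and ribosome biogenesis genes were lower as groups. In G2/M cell cycle genes 23 of 24 members had a mean ratio below 0 (adjusted p = 0.00105, median -0.34, and adjusted p = 0.713 with an estimated correlation). The medians were -0.70, 0.02 and -0.25 at 3, 6 and 12 h, and the call was lost without the 3 h pair (adjusted p = 0.678). At 6 h and 12 h these medians lay above 40.7 and 47.2 percent of random lists, so only the 3 h median stood apart. KIF20A (-0.99), KIF11 (-0.76), KIF23 (-0.69) and CKS2 (-0.54) were the largest. FOXO target genes had a median of -0.34 (adjusted p = 0.0227, and adjusted p = 0.678 with an estimated correlation), led by KLHL24 (-1.15), CCNG2 (-0.90), KLF2 (-0.83) and HBP1 (-0.79), with 11 of 16 members below 0. The FOXO medians at 3, 6 and 12 h lay above 1.48, 2.17 and 49.3 percent of random lists. Heat shock genes had 12 of 13 members below 0 and a median of -0.20 (adjusted p = 0.0262, and adjusted p = 0.678 with an estimated correlation). That median lay above 6.41 percent of random lists. HSPA4L (-0.56), FKBP4 (-0.55), HSPA4 (-0.52) and CHORDC1 (-0.45) stood lowest. The FOXO and heat shock calls were lost without the 3 h pair (adjusted p = 0.499 and 0.201) without the 6 h pair (0.0599 and 0.0707), without _x_at and _s_at probe sets (0.0792 and 0.503) and under a stricter filter (0.1002 and 0.0506). Ribosome biogenesis and MYC target genes had 16 of 17 members below 0 and medians of 0.05, -0.19 and -0.62 (adjusted p = 0.0316, and adjusted p = 0.713 with an estimated correlation). Their largest mean ratios were those of RRS1 (-1.02), MYBBP1A (-0.42) and FBL (-0.39), and RRP12 at 0.50 was the exception, with a second probe set at -0.35. This call was lost without the 12 h pair (adjusted p = 0.503), without the 6 h pair (0.0923) and with the ribosomal RNA covariate (0.194). No member of these 4 lists passed over all genes or when adjusted over the list alone.

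**Figure D3:**
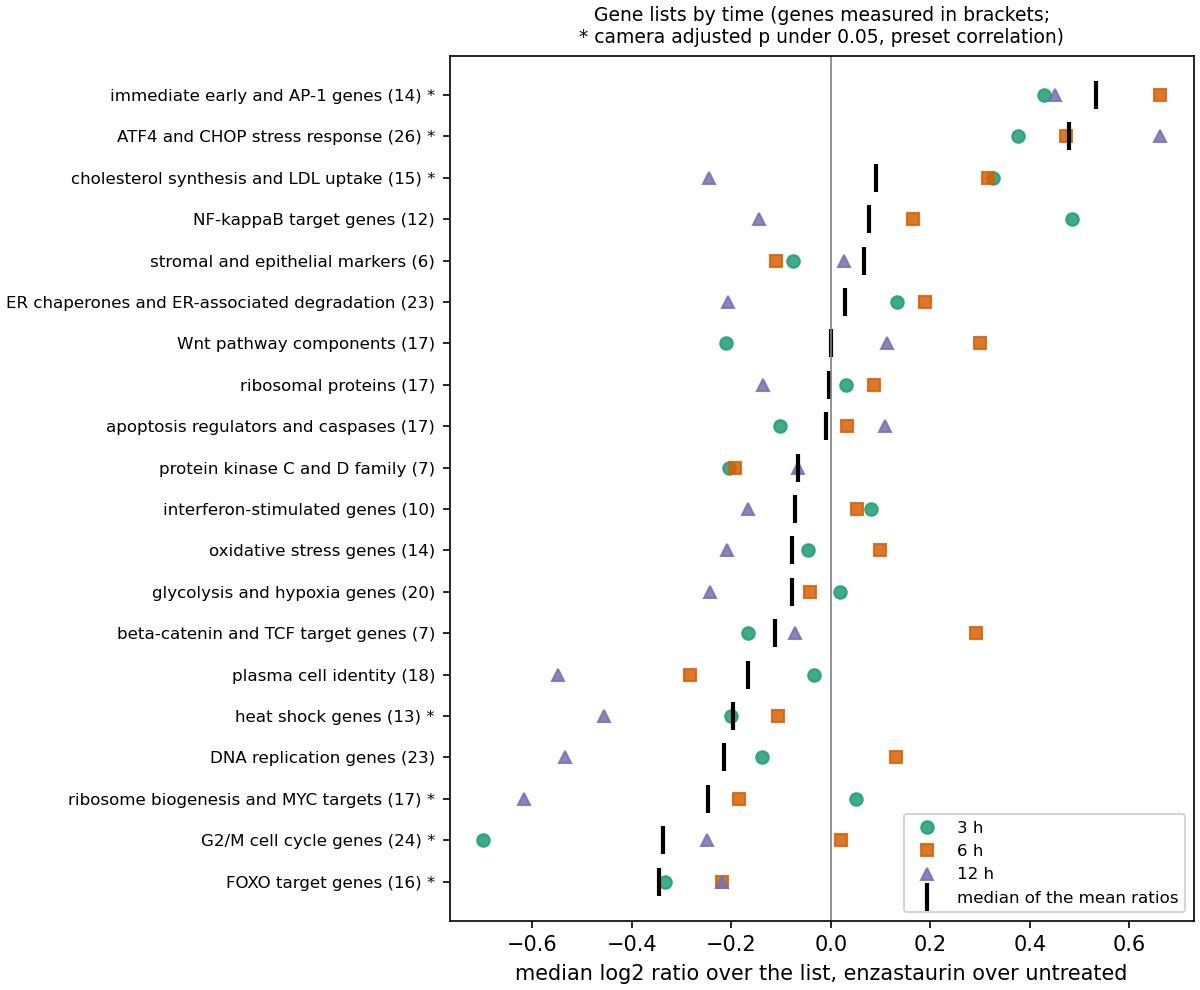
Median log2 ratio of enzastaurin over untreated cells (x axis) of 20 of the 21 tested gene lists (y axis, number of measured genes in brackets) at 3, 6 and 12 h (symbols), with the median of the mean ratios as a black bar and an asterisk for an adjusted p under 0.05 in camera at the preset correlation. The ATF4 and CHOP list lies at 0.38, 0.47 and 0.66, and the G2/M list at -0.70, 0.02 and -0.25.

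The lists of beta-catenin targets, Wnt components and the protein kinase C and D family were not called in the reported fit. Beta-catenin targets were called with every probe set tested. Beta-catenin and TCF target genes had 7 measured members, 3 above and 4 below 0 (adjusted p = 0.980, median -0.11, test direction up). Over all genes none passed, and adjusted over the list alone JUN passed upward and MYC downward, beside BIRC5 (-0.56) and PPARD (0.48). The 2 other kept BIRC5 probe sets had mean ratios of 0.01 and -0.04. Wnt pathway components had a median of 0.00 over 17 genes (adjusted p = 0.564), with FZD6 at 0.78, TLE3 at -0.60, DVL3 at 0.33 and GSK3A at -0.28, and the other kept probe sets of TLE3 were at 0.24 and -0.44. Among 7 protein kinase C and D family genes (median -0.07, test direction up, adjusted p = 0.977), MARCKS, a substrate of the kinase, had ratios of -0.96, 1.29 and 1.75, PRKCA a mean of -0.54 and PRKCI 0.25. No member of these 2 lists passed over all genes or when adjusted over the list alone.

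Apoptosis regulators and caspases had a median of -0.01 over 17 genes (mean 0.07, test direction up, adjusted p = 0.408), with no member past the test over all genes or when adjusted over the list alone. CASP8 had a mean ratio of 0.88, BCL2L11 0.79, CASP2 0.41 and BCL2 -0.63, with a second BCL2 probe set at 0.20.

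Plasma cell identity genes had 11 of 18 members below 0 and medians of -0.03, -0.28 and -0.55 (adjusted p = 0.204). No member passed over all genes, and TNFRSF17 (-1.37), ITGA4 (-1.28) and IRF4 (-1.13) passed downward when adjusted over the list alone, with SDC1, which encodes CD138, at -0.66. Without the 3 h pair the list was called by camera at the preset correlation (adjusted p = 0.0487). With an estimated correlation its camera adjusted p over all 3 pairs was 0.734. In NF-kappaB target genes (median 0.08, adjusted p = 0.0527), none passed over all genes, and CCL4 passed upward and TNFAIP3 (-1.03) downward when adjusted over the list alone, beside NFKBIA (0.79) and ICAM1 (0.57). DNA replication genes had 20 of 23 members below 0 and a median of -0.21 (adjusted p = 0.0527). UNG (-0.70), MCM7 (-0.59), MCM5 (-0.48) and FEN1 (-0.33) were the largest, the second FEN1 probe set was at 0.11, and none passed over all genes or when adjusted over the list alone.

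The remaining lists were not called. Among interferon-stimulated genes (median -0.07, mean 0.11, test direction up, adjusted p = 0.267) no member passed over all genes, and OAS3 and OAS1 (1.03) passed upward and BST2 (-1.33) downward when adjusted over the list alone, with IRF9 at 0.33. Glycolysis and hypoxia genes (median -0.08, adjusted p = 0.390) had none over all genes, and ADM (-1.48) downward when adjusted over the list alone, beside VEGFA (1.21), MXI1 (-0.90) and PDK1 (-0.63). Oxidative stress genes (median -0.08, test direction up, adjusted p = 0.980) held TKT (-2.11), TXNRD1 (-0.64), HMOX1 (0.45) and GCLM (0.41), with none past the test over all genes or adjusted over the list alone. Ribosomal proteins had a median of -0.00 (test direction up, adjusted p = 0.977), with RPL19 at -0.18, RPL3 at -0.16, RPL7 at -0.13 and RPL8 at 0.13, and again none passed over all genes or adjusted over the list alone.

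Markers of other cell types were looked at on all 6 arrays. Monocyte and macrophage markers had no measured member, and 11 with a probe set had median intensities of 18.6 to 28.0 on each array. Of T and NK cell markers 2 were measured, TRAT1 (-0.59) and CD8B (0.32), and 16 with a probe set had medians of 25.8 to 34.0. Stromal and epithelial markers had 6 measured members and were not called (adjusted p = 0.917, median 0.07, mean -0.06, test direction up), with SPARC at -0.93, FN1 at 0.28, VIM at 0.21 and COL1A2 at 0.10. Mean intensities were 3246 for VIM, 237 for SPARC and 190 for FN1. None of these members passed over all genes or when adjusted over the list alone.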

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

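Of the tests in this part, those of exchanged 3 h labels, of a response that differs with time, of RNA degradation at 12 h and of other splits for the gene count were chosen after the result was seen.

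The effect of enzastaurin differed between times, by the test of its slope, in 98 genes, of which 7 were left with quantile normalization and 0 with equal medians of the kept genes. The slope per doubling of hours was 2.73 for CD6, 2.64 for MTSS1, 2.43 for SERPINA1, 2.05 for DEPP1 and 2.04 for IGLJ3. It was -2.22 for KCNN3, -2.05 for PTPN6, -1.93 for HLA-DOB, -1.90 for HLA-DPB1 and -1.77 for TKT. The sizes for CD6, MTSS1, SERPINA1, KCNN3 and HLA-DOB are not exact, since their lowest intensities lay near or below the level of monocyte markers. Log2 ratios at 3 h ran opposite to those at 6 h and 12 h across genes, with correlations of -0.21 and -0.14. The ATF4 and CHOP genes speak against exchanged labels at 3 h, since their median ratio at 3 h was 0.38, on the same side as at 6 h and 12 h. That median was known when the test was chosen, and the ribosomal RNA intensities place each 3 h array with the other treatment. Exchanged labels are therefore not excluded. A split of the arrays by ribosomal RNA intensity predicts that the low-against-high contrasts within the untreated and within the enzastaurin arrays, which share no array, correlate above every other pairing. They correlated at 0.14, and the untreated 12 h and enzastaurin 3 h arrays, each set against the rest of its treatment, correlated at 0.41, so this stays open. A biological change of the response with time cannot be told apart from the ribosomal RNA split, because the time and the ribosomal RNA difference of the 3 pairs correlate at -0.80.

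A second pattern was the excess of genes at least 2-fold lower over higher at 12 h (712 against 265). RNA degradation in the 12 h enzastaurin sample is argued against by its ACTB 3' to 5' log2 ratio of 0.86, below the lowest untreated value of 1.16, and its GAPDH ratio of 0.24 lay within the untreated range of 0.23 to 0.30. A difference in scaling between the arrays cannot be told apart from a broad fall of abundant transcripts in these cells, which was not tested. With equal medians of the kept genes 49.7 percent were lower, but that centring itself sets the balance, and 76.4 percent were lower with equal medians of all probe sets and 58.9 with quantile normalization.

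The last pattern was the call of 4 genes and 7 lists for the treatment. The 6 arrays make 10 splits, too few for a share under 0.05. Of these, 1 split, the real one, gave 4 genes, and the highest other gave 0, but 6 of the others part only 1 time-matched pair, and without the time block the real split and 1 other both gave 2. For lists, 1 split gave 7, the real one, and the highest other gave 5. At an unadjusted p under 0.05 the split that exchanges the 3 h arrays gave 959 genes against 370 for the real split. The split that gave 959 goes with both a structure of the arrays and a response that turns after 3 h. Splits that part only the 12 h pair gave 843, also more than the real split. With the time block, splits that part the same single pair are the same test, so fewer than 10 separate tests were compared.

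Among 33 AFFX control probe sets above the intensity filter, 1 was higher on every enzastaurin array than on every untreated array, the 5' probe set of GAPDH, by 0.19 on the log2 scale. Chance gives that outcome in 5 percent of probe sets.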

How the results depend on the processing

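The ribosomal RNA covariate, equal medians of the kept genes and 12 h against 3 h without the 6 h pair were chosen after seeing the data. RND3, BHLHE40, LMNB1 and TNFAIP8 kept their sign wherever they were measured, and no named gene past a test changed sign. The count of 4 genes became 1 with equal medians of all probe sets, without a filter and with every probe set tested, 2 without _x_at and _s_at probe sets, 2 without the replicate block (RND3 and TNFAIP8) and 0 with a variance prior without trend. Leaving out 1 pair gave 0 (without 6 h or 12 h) to 247 genes (without 3 h), and the ribosomal RNA covariate gave 74, which include all 4 and share 53 with the 247. The prior of the covariate fit was estimated as infinite, and that of the fit without the 3 h pair had 16.86 degrees of freedom. Neither the 74 nor the 247 can therefore be set directly against the 4. Time-matched arrays did not deviate together: the correlations across genes of their deviations from the treatment means were -0.14, -0.05 and -0.26 at 3, 6 and 12 h. The 98 slopes became 7 with quantile normalization, 167 with equal medians of all probe sets, 151 without a filter, 181 with every probe set tested, 57 without _x_at and _s_at probe sets and 0 with equal medians of the kept genes. In that last setting the prior had 8.04 degrees of freedom, against a prior estimated as infinite in the reported fit, and all 98 slopes kept their sign. The 0 genes between 12 h and 3 h stayed at 0 in every setting run, with 87 to 308 genes at an unadjusted p under 0.05 in limma, the latter without a filter. Genes at least 2-fold apart numbered 310 at 3 h, 603 at 6 h and 977 at 12 h. These became 204 at 3 h with log2 of intensity plus 16, 1578, 2061 and 2224 without a filter, 178 and 384 at 3 h and 6 h under the stricter filter, 577, 1053 and 1589 with every probe set, 196, 385 and 601 without _x_at and _s_at probe sets, and 49, 139 and 258 at 3-fold. The share of lower genes, 58.4, 36.5 and 72.9 percent, was 47.3, 46.9 and 58.9 with quantile normalization, 48.0, 50.5 and 76.4 with equal medians of all probe sets, and 54.1, 41.0 and 49.7 with equal medians of the kept genes, which shifted the median ratio at 12 h from -0.18 to 0.02. The share at 12 h was 56.3 without a filter.

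The count of 7 lists became 0 with an estimated correlation and 4 to 8 with 1 pair left out. Adjusted p with an estimated correlation was 0.592 for the ATF4 and CHOP and the immediate early lists, 0.713 for the G2/M, cholesterol and ribosome biogenesis lists and 0.678 for the FOXO and heat shock lists. The ATF4 and CHOP call held in every other setting. Without _x_at and _s_at probe sets the immediate early (0.0641), cholesterol and FOXO (both 0.0792) and heat shock (0.503) calls ended, and plasma cell identity (0.0346) and glycolysis and hypoxia (0.00585) were called. FOXO was at 0.0855 without a filter and 0.1002 under the stricter filter, heat shock at 0.0506 under the stricter filter and 0.0701 with the median over probe sets, and ribosome biogenesis at 0.194 with the ribosomal RNA covariate. With every probe set tested, ER chaperones (0.00690), beta-catenin targets and DNA replication (both 0.0116) were called, and with the median over probe sets ER chaperones were at 0.0314. DNA replication was called with equal medians of all probe sets (0.0472) and without a filter (0.0114). NF-kappaB targets were called with equal medians of all probe sets (0.0472), without the replicate block (0.0421), with the median over probe sets (0.0153) and with the covariate (0.00212). With 1 pair left out, adjusted p ran from 0.0178 to 0.961 for ER chaperones, 3.82e-06 to 0.678 for G2/M, 0.0218 to 0.755 for DNA replication, 0.000117 to 0.407 for cholesterol, 0.0487 to 0.740 for plasma cell identity, 0.00721 to 0.499 for NF-kappaB targets, 0.000117 to 0.499 for FOXO targets, 0.0274 to 0.201 for heat shock and 0.0308 to 0.503 for ribosome biogenesis. The other calls were the same, and the cause of these changes was not tested. Intensities near the filter limit what could be measured, and TP73 and CCND1 lay below it.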

Other observations

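Both hypotheses in this part were drawn from genes seen to be high or low, and each was then tested on other genes of the same group, with the prediction written before those other genes were looked at.

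Several genes of the lysosome, the organelle that degrades proteins and lipids, had ratios above 0 at all 3 times. Log2 ratios at 3, 6 and 12 h were 0.27, 1.37 and 1.82 for the protease CTSB, 0.45, 1.52 and 1.91 for LGMN, 0.46, 0.95 and 0.91 for NPC2, 1.27, 1.53 and 0.65 for NEU1 and 0.02, 1.31 and 1.35 for SMPDL3A. Among the other kept probe sets of CTSB, a strong one had -0.09, -0.29 and 0.66. Another strong one had 0.11, 1.69 and 1.96, and a weaker one had 0.81, 1.43 and 1.46. The hypothesis that lysosomal genes rise as a group at both 6 h and 12 h was not borne out: 35 other lysosomal genes had a median of 0.0953 at 6 h and -0.0797 at 12 h, above 64.3 and 87.3 percent of random lists. At 3 h their median was 0.23, above 99.9 percent. Over the 3 times the median of their mean ratios was 0.10, above 99.6 percent, with a camera p of 0.00821 and of 0.0923 with an estimated correlation.

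Several genes of protein entry, folding, sugar trimming and degradation at the ER were low at 6 h and 12 h but not at 3 h. Beside PDIA3, log2 ratios at 3, 6 and 12 h were 0.36, -2.38 and -1.98 for FKBP2, 0.10, -2.37 and -1.19 for the glucosidase GANAB and 0.37, -1.01 and -1.48 for MOGS. They were 0.06, -1.90 and -2.86 for RRBP1, -0.02, -1.03 and -2.21 for UBE2J1 and 0.60, -1.80 and -1.78 for ERP29, and 1 weaker probe set of RRBP1 had -0.57, -0.08 and 0.23. The hypothesis that genes of ER entry, folding and glycosylation fall as a group was not borne out: 44 others had a median of 0.0827 at 6 h and -0.24 at 12 h, where the median of all kept genes was -0.18.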
